A study of Homo sapiens with 8 samples.

How the data were processed

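Total RNA of human H9 embryonic stem cells and of cells derived from pluripotent stem cells was measured on 8 Affymetrix Human Genome U133 arrays of the A design, a 1-colour short-oligonucleotide platform on which each transcript is read by probe sets placed mostly near its 3′ end. The labels give 3 groups: undifferentiated H9 cells (2 arrays), embryoid bodies after 10 days in blood-inducing conditions (3 arrays) and CD31-positive CD45-negative cells sorted from such embryoid bodies (3 arrays), whose sample titles also carry the letters PFV; their meaning is not given in the sources used here. They call the arrays of a group biological replicates and do not say which culture each came from, so that p-values measure the spread between these arrays only.

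The deposited table holds log2 values for 22283 probe sets that the authors made with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes, which give no version. In the deposited values the median of every probe set over the 8 arrays is 0, so a centring step per probe set followed RMA; no label records that step. The log base is not stated and is taken as 2, which is what RMA gives. Differences between arrays are kept by the centring, but the level of a probe set and its signal over background are lost. Values ran from −4.75 to 5.36, and the array medians lay between −0.03 and 0.04. For arrays no depth applies, and the number of arrays limits the precision.

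Of the probe sets, 68 control probe sets were left out of the tests of genes. Among the others, 19065 had exactly 1 gene symbol in the platform annotation, 1043 had several and 2107 had none; the last 2 kinds were left unnamed. An Entrez identifier in the reference gene table was found for 19053 of the single-gene probe sets, and no symbol needed an update. Each gene's value was the mean of its single-gene probe sets, which gave 11963 genes, 4310 of them with at least 2 probe sets. The plan had been to take each gene's brightest probe set and to try a filter on dim genes, but neither can be computed from centred values; the mean had been listed beforehand as an alternative. Called probe sets of 1 gene pointed in opposite directions for 15 genes between embryoid bodies and H9 cells and for 41 genes between sorted cells and embryoid bodies.

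Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in one model of all 8 arrays without further covariates, with Benjamini-Hochberg adjustment over the genes of each comparison and an adjusted p threshold of 0.05. A difference is given on the log2 scale as the first group minus the second, with the standard error (SE) from the moderated variance. The genes of 28 lists (lineages, Notch parts and targets, signalling pathways, metabolic and technical sets) were fixed before the data were examined, and each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera was repeated with the correlation estimated per list, and limma's fry was run as another set test; fry asks whether the genes of a list move one way on balance and does not compare them with other genes. The rule for named genes was also fixed beforehand. HES1 and the sort markers PECAM1 (CD31) and PTPRC (CD45) are always named. So are the 5 largest increases and the 5 largest decreases among called genes whose arrays do not overlap between the groups. From each described list, up to 4 called members of largest size may be named. Not all of these are named, and in places a larger one was left out for a smaller one. Where no member of a list passed, the member with the smallest adjusted p is given as a value. All called members of the Notch lists may be named, and the comparison of sorted cells with H9 cells may be left as counts.

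The alternatives were other scalings of the arrays (equal medians, quantile normalization), single probe sets in place of genes, trended and robust variances, array weights, a fit of only the 2 groups compared, the replicate number as a block, a fold minimum, limma's treat at 1.5-fold, and leaving out each array in turn. After the data had been seen, 4 more were added: leaving out both replicate 3 arrays, the most variable probe set per gene, the mean without probe sets whose name ends in _x_at, and a replicate block with only the 2 groups compared. Embryoid bodies and sorted cells share replicate numbers 1 to 3. The correlation of same-numbered arrays' deviations from their group means, across genes, was 0.16, 0.13 and 0.12. Every array of these 2 groups correlated best with its own number in the other group. These matches are not independent, because the deviations within a group balance out. A larger value also arose between arrays that share no number (below). Pairing by number was therefore possible but not shown, and the labels do not give it. The words paired groups below stand for this possible pairing. The model fixed beforehand has no block, so its standard errors, p-values and counts leave any pairing out. Values with the block are given where it changes a call. The H9 arrays showed no such pairing (same-number correlations with the embryoid bodies −0.09 and 0.02), and the correlation of 0.21 between embryoid body array 3 and H9 array 1, which share no number, was larger than those of the pairs. The block fit of all 8 arrays, written before the data were examined, nevertheless placed H9 arrays 1 and 2 in blocks 1 and 2; the fit of the 2 paired groups alone does not.

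The functions were tested on simulated data with the spread of the real 11963 genes and 200 changed genes. For sorted cells against embryoid bodies, 74% of 50 genes changed 1.5-fold and 100% of 50 genes changed 2-fold were called, and 6 unchanged genes were. For embryoid bodies against H9 cells, 68% of the 50 genes changed 1.5-fold and 98% of those changed 2-fold were called, with 7 unchanged genes. For sorted cells against H9 cells these shares were 58% and 98%, with 12 unchanged genes. These data had independent arrays. In 10 simulated runs without any change, independent arrays gave 5%, 4.7% and 4.9% of genes an unadjusted p under 0.05 in embryoid bodies against H9 cells, sorted cells against embryoid bodies and sorted cells against H9 cells. The replicate 3 array of each group of 3 was also simulated as a mixture of replicates 1 and 2 plus noise (noise share 0.3). The shares of genes with an unadjusted p under 0.05 were then 16.1%, 20.3% and 15.9%. The highest numbers of called genes in a run were 27, 236 and 44. Whether this noise matches that of the real replicate 3 arrays was not tested. These values therefore hold for the simulated setting and are not error rates of the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.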

Results

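The study concerns Notch signalling in blood differentiation of human pluripotent stem cells. Expression was measured in undifferentiated H9 cells, an established human embryonic stem cell line (2 arrays). It was also measured in embryoid bodies, which are floating aggregates of differentiating cells, after 10 days with haematopoietic cytokines (3 arrays), and in a CD31-positive CD45-negative fraction isolated from such embryoid bodies (3 arrays). The design describes this fraction as precursors able to form both blood and endothelium. All values are centred log2 intensities, so only differences between arrays can be read from them.

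The third arrays of both groups of 3 had a particular position. On 632 probe sets, replicates 1 and 2 of the embryoid bodies differed by more than 1 log2 unit, and replicate 3 lay between them on 631 of these (99.8%). In the sorted cells replicate 3 lay between the first 2 on 251 of 254 such probe sets (98.8%). Among the probe sets on which the 3 arrays of a group spread over more than 1 log2 unit, replicate 3 was in the middle for 99.5% in the embryoid bodies and for 94.7% in the sorted cells, where independent arrays would each be in the middle for about 1 in 3. The root mean square distance of replicate 3 from the log2 of the linear mean of replicates 1 and 2 was 0.19 in the embryoid bodies and 0.25 in the sorted cells, against median gaps between the first 2 of 1.30 and 1.23. The totals of genes and lists below are therefore also given without both replicate 3 arrays, an alternative chosen after this was seen, and so are the counts within lists that it moved by over 1.5 times.

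**Figure D1:**
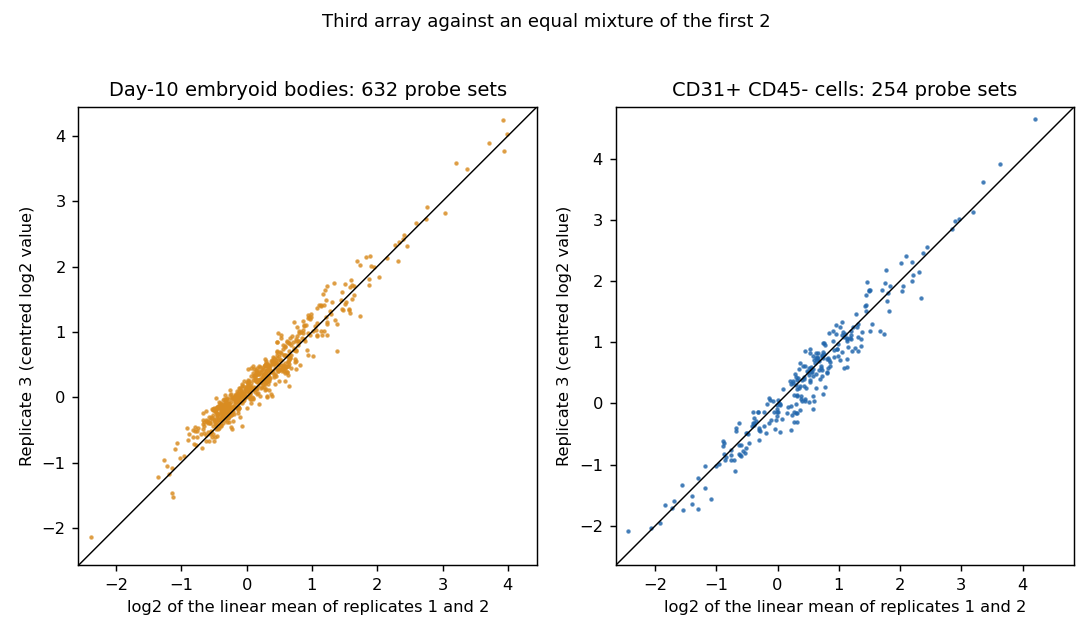
Each point is a probe set on which replicates 1 and 2 of a group differed by more than 1 log2 unit (632 for embryoid bodies, left; 254 for sorted cells, right); the x axis is the log2 of the linear mean of replicates 1 and 2, the y axis is the centred log2 value of replicate 3, and the line marks equality. The points lie along the line in both groups, with root mean square distances of 0.19 and 0.25.

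The first comparison asked how embryoid bodies after 10 days of culture differed from undifferentiated H9 cells. The called genes of the pluripotency and cell cycle lists were all lower in the embryoid bodies, and those of the mesoderm, HOX and BMP lists were all higher. In the pluripotency list, 12 of 21 measured genes fell and 0 rose (13 passed when adjusted over the list alone). LEFTY1, an antagonist of Nodal signalling, had a log2 difference of −5.29 (SE 0.13) and NANOG, a core pluripotency factor, one of −4.37 (SE 0.40). DPPA4 differed by −3.32 (SE 0.15) and UTF1 by −2.73 (SE 0.21). The other 9 measured genes, SOX2 among them, were not called. POU5F1, SALL4 and ZFP42 had no probe set of their own among those named. The list's camera adjusted p was 1.73e-10 and its adjusted p = 0.0939 with an estimated correlation. In the cell cycle list 21 of 37 genes fell and 0 rose (25 adjusted over the list alone; camera adjusted p = 1.04e-13, adjusted p = 0.0803 with an estimated correlation). BUB1B, a spindle checkpoint kinase, differed by −1.67 (SE 0.11), CDC20 by −1.32 (SE 0.18) and cyclin B1 (CCNB1) by −1.31 (SE 0.12).

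In the primitive streak and mesoderm list 8 of 17 genes rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 0.000136, adjusted p = 0.108 with an estimated correlation). The transcription factors HAND1, ISL1, TBX3 and SNAI2 rose by 2.96 (SE 0.25), 2.49 (SE 0.19), 1.89 (SE 0.23) and 1.84 (SE 0.11). Of 31 mesenchyme and smooth muscle genes, 15 rose and 4 fell (22 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.0939 with an estimated correlation). Decorin (DCN) and collagen COL3A1 rose by 1.83 (SE 0.27) and 1.63 (SE 0.16), whereas TAGLN, an actin-binding protein of smooth muscle, differed by −2.49 (SE 0.20). In the cardiac list 4 of 21 genes rose and 1 fell (6 adjusted over the list alone; camera adjusted p = 0.0423, adjusted p = 0.31 with an estimated correlation); atrial myosin light chain MYL7 rose 2.82-fold and the natriuretic peptide gene NPPB differed by −1.96 (SE 0.16). Among HOX genes 8 of 18 rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 0.000428, adjusted p = 0.0803 with an estimated correlation), with HOXC6 highest at 1.83 (SE 0.13).

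Signalling lists moved as well. In the BMP and TGF-β list 9 of 31 genes rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.00144, adjusted p = 0.0803 with an estimated correlation). Its leading member ID3, a target of BMP signalling, rose by 1.82 (SE 0.10), and the co-receptor gene TGFBR3 rose by 1.46 (SE 0.23). WNT pathway genes went both ways, 8 of 29 rising and 3 falling (17 adjusted over the list alone; camera adjusted p = 0.00721, adjusted p = 0.0939 with an estimated correlation). The receptor genes FZD2 and FZD5 differed by 1.73 (SE 0.26) and −2.56 (SE 0.18), and the transcription factor genes LEF1 and TCF7L1 by 1.17 (SE 0.09) and −1.01 (SE 0.11). Of 27 immediate-early and stress genes, which respond within minutes to handling as well as to growth factors, 11 rose and 2 fell (18 adjusted over the list alone; camera adjusted p = 9.51e-05, adjusted p = 0.0803 with an estimated correlation). ATF3, FOSB and FOS rose by 1.52 (SE 0.11), 1.49 (SE 0.09) and 1.26 (SE 0.18), and IER3 differed by −1.47 (SE 0.23).

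Among Notch genes, 4 of 10 measured ligands and receptors rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.0028, adjusted p = 0.0939 with an estimated correlation). These were DLK1 with 1.38 (SE 0.18), NOTCH2 with 0.67 (SE 0.09), DLL3 with 0.61 (SE 0.08) and DLK2 with 0.36 (SE 0.09); DLK1 and DLK2 encode non-canonical ligands. The Notch machinery list did not pass (2 of 27 rose and 3 fell, 5 adjusted over the list alone; camera adjusted p = 0.92). Its median and mean were 0.01 and 0.00, and fry pointed down where camera pointed up. Within it RBPJ, the DNA-binding partner of the Notch intracellular domain, differed by −1.25 (SE 0.10). The Notch target list did not pass either (camera adjusted p = 0.1), with 4 of 14 genes rising and 2 falling (7 adjusted over the list alone). Fry, which does not compare a list with other genes, passed the target list upward (adjusted p = 0.00254). HEY1, a transcriptional repressor, rose by 2.30 (SE 0.17) and GATA3 by 1.31 (SE 0.11). CDKN1A and cyclin D1 (CCND1) differed by −1.24 (SE 0.10) and −0.63 (SE 0.10). HES1 itself differed by 0.16 (SE 0.12, limma adjusted p = 0.393), and was called only with its most variable probe set, among the alternatives run (0.68, adjusted p = 0.0479). The ligand genes DLL1 and DLL4 had no probe set of their own among those named, and neither had HES4, HES5, HES6, HES7 or RUNX1.

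Lists of blood and endothelium differed in how many genes passed at this step. Across all genes, 2220 of 11963 were called, 829 of them higher. In the list of hemogenic regulators, transcription factors of the transition from endothelium to blood, 6 of 25 genes rose and 0 fell (1 rose without both replicate 3 arrays; 6 adjusted over the list alone; camera adjusted p = 0.00203, adjusted p = 0.118 with an estimated correlation). MEIS1 rose by 1.66 (SE 0.22), LMO2 by 0.77 (SE 0.15) and GATA2 by 0.68 (SE 0.12). In the arterial list 3 of 16 genes rose and 0 fell (3 adjusted over the list alone; camera adjusted p = 0.00721, adjusted p = 0.184 with an estimated correlation). They include HEY1 and IGFBP3, at 0.97 (SE 0.14). The endothelial list did not pass (4 of 38 rose and 1 fell, 5 adjusted over the list alone; camera adjusted p = 0.0819). TEK, an angiopoietin receptor, rose by 0.53 (SE 0.08) and PODXL, a sialomucin of endothelium and of pluripotent cells, differed by −0.89 (SE 0.23). The erythroid list had 2 of 14 genes rising and 2 falling (10 adjusted over the list alone; camera adjusted p = 0.0919); embryonic globin HBE1 rose by 0.85 (SE 0.09) and the transferrin receptor TFRC differed by −0.63 (SE 0.08). The megakaryocyte list had 2 of 17 genes rising and 0 falling (2 adjusted over the list alone; camera adjusted p = 0.63), and its median of 0.02 and mean of −0.01 differed in sign. CLEC1B rose by 0.68 (SE 0.15). In the pan-leukocyte list only SPN rose, by 0.35 (SE 0.09), of 24 genes (0 adjusted over the list alone; camera adjusted p = 0.0969). Of 23 myeloid genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.385); CSF1R had the smallest adjusted p, 0.0622, with a difference of 0.27 (SE 0.09). The sort markers PECAM1 and PTPRC differed by −0.02 (SE 0.09, adjusted p = 0.908) and 0.17 (SE 0.07, adjusted p = 0.141).

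Markers of other lineages were mixed. Of 25 neuroectoderm genes 4 rose and 3 fell (8 adjusted over the list alone; camera adjusted p = 0.0919). MSX1, a homeobox gene of neural crest and also of mesoderm, was the largest increase of the comparison at 3.63 (SE 0.26), whereas PAX6 differed by −0.83 (SE 0.15). Of 24 endoderm and liver genes 1 rose and 3 fell (4 adjusted over the list alone; camera adjusted p = 0.205). GATA6 rose by 1.87 (SE 0.49) and fibrinogen FGG differed by −1.65 (SE 0.38). Of 24 genes of surface epithelium and trophoblast 3 rose and 4 fell (8 adjusted over the list alone; camera adjusted p = 0.92, pointing down while the list's median was 0.08). CGA, the shared subunit of the glycoprotein hormones, differed by −4.84 (SE 0.43). The other genes with the largest increases were the hormone gene SST (3.43, SE 0.11), the uncharacterised LOC728392 (2.86, SE 0.56) and the desaturase gene SCD5 (2.58, SE 0.10). The other largest decreases were osteopontin (SPP1, −4.32, SE 0.22) and the NKG2D ligand gene MICB (−3.97, SE 0.20).

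In all, 2220 of 11963 genes differed between embryoid bodies and H9 cells (limma, adjusted p threshold 0.05), 829 higher and 1391 lower, of which 125 and 261 differed at least 2-fold; 14 of the 28 lists passed, 11 upward and 3 downward, 0 passed with camera at an estimated correlation, and fry passed 17. Without both replicate 3 arrays 835 genes were called, 236 higher and 599 lower, 831 of them among the 2220 and 310 among the 386 with at least 2-fold differences, and the same 14 lists passed; 743 genes were called without the first H9 array, 1006 without the second and 1403 without the third embryoid body array. Of the genes named in this comparison, the calls of DLK2, LMO2, GATA2, PODXL, CLEC1B, SPN, GATA6, FGG and LOC728392 ended without the third arrays. Without the first H9 array, the calls of all of these except LMO2 ended, as did those of MYL7, TEK and PAX6 (adjusted p = 0.0578, 0.0549 and 0.0563); that of LMO2 ended without the second H9 array (adjusted p = 0.0804). The 9 ribosomal RNA control probe sets named HUMRGE, Hs18SrRNA or Hs28SrRNA were lower in embryoid bodies than in H9 cells by a mean of 1.27. This value moved with all of the differences above (group difference −1.27, exact permutation p = 0.1 two-sided, the smallest that 3 against 2 arrays allow). The M27830 control probe sets, also of ribosomal RNA, were not in this mean and went both ways. M27830_M had 0.636, 0.738 and 0.624 on the embryoid body arrays against −0.002 and −0.103 on the H9 arrays. M27830_3 was also higher, and M27830_5 was lower, with 0.017, −0.605 and −0.267 against 0.296 and 0.225.

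Within the lists, fewer genes of embryoid bodies against H9 cells were called without both replicate 3 arrays. Rising genes went from 8 to 4 in the mesoderm list, from 15 to 8 in mesenchyme, from 4 to 1 in the cardiac list, from 8 to 2 among HOX genes, from 9 to 4 in the BMP and TGF-β list, from 8 to 3 in the WNT list and from 11 to 5 among immediate-early and stress genes. They went from 4 to 2 among Notch targets, from 2 to 0 in the Notch machinery, from 4 to 1 in the endothelial list, from 2 to 1 in the erythroid, from 2 to 0 in the megakaryocyte, from 1 to 0 in the pan-leukocyte, from 4 to 2 in the neuroectoderm and from 1 to 0 in the endoderm list. Falling genes went from 4 to 2 in mesenchyme and in the epithelium and trophoblast list, from 3 to 1 in the Notch machinery, from 3 to 0 in the endoderm list, from 2 to 1 in the erythroid and the immediate-early list and from 1 to 0 in the endothelial list.

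**Figure D2:**
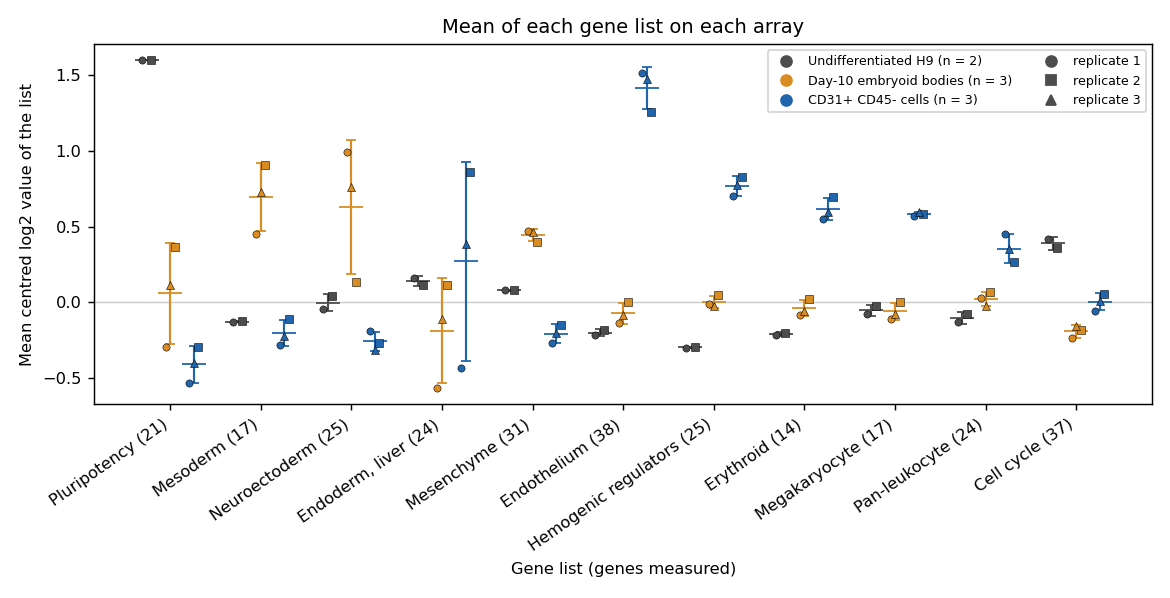
Mean centred log2 value (y axis) of the measured genes of 11 of the gene lists (x axis, number of genes in parentheses) on each array; symbols are replicates, colours are groups, horizontal bars are group means and error bars are SD (n = 2, 3 and 3). The endothelial mean lies between 1.26 and 1.52 on the sorted cell arrays and at or below 0.00 on the others, and the neuroectoderm mean on the embryoid body arrays runs from 0.14 to 0.99.

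The second comparison asked what set the CD31-positive CD45-negative fraction apart from whole embryoid bodies. Of 38 measured endothelial genes, 31 rose and 2 fell (34 adjusted over the list alone; camera adjusted p = 3.81e-21, adjusted p = 0.0714 with an estimated correlation). VE-cadherin (CDH5) was higher by 4.73 (SE 0.11), the receptor gene TIE1 by 3.48 (SE 0.24) and the adhesion receptor gene ADGRL4 by 3.44 (SE 0.21). PECAM1, which encodes the CD31 antigen used for the sort, was higher by 3.33 (SE 0.08), which is 10-fold. This is the mean of probe sets that gave 1.622, 3.439 and 4.925. PECAM1 is itself in the endothelial list, and the cells were chosen by CD31, so the rise of this list follows in part from the sort. The titles of these samples also carry the letters PFV, whose meaning is not given in the sources used here, so whether further antigens, CDH5 or KDR for example, were used for sorting is not known. PTPRC, which encodes the CD45 antigen the sort excluded, differed by −0.11 (SE 0.07, adjusted p = 0.225). In the arterial list 8 of 16 genes rose and 1 fell (12 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.231 with an estimated correlation). SOX17, the gap junction gene GJA4 and ephrin-B2 (EFNB2) rose by 2.99 (SE 0.32), 1.85 (SE 0.14) and 1.49 (SE 0.20), and IGFBP3 differed by −1.67 (SE 0.13).

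In the list of hemogenic regulators 13 of 25 genes rose and 1 fell (14 adjusted over the list alone; camera adjusted p = 3.63e-06, adjusted p = 0.0714 with an estimated correlation). LMO2, a bridging factor in blood and endothelial transcription complexes, was higher by 4.50 (SE 0.13), HHEX by 2.84 (SE 0.19), the flow-responsive KLF2 by 2.23 (SE 0.15) and LYL1 by 1.74 (SE 0.12). The list shares TAL1, FLI1 and ERG with the endothelial list and MECOM with the arterial list. It also shares NFE2 with the megakaryocyte and KLF1 with the erythroid list, so it is not fully separate from these lists. Of 14 erythroid genes 8 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.000205, adjusted p = 0.181 with an estimated correlation). The embryonic globins HBE1 and HBZ rose by 2.35 (SE 0.08) and 1.93 (SE 0.16), the erythroid membrane gene RHAG by 1.73 (SE 0.13) and the haem synthesis enzyme gene ALAS2 by 1.02 (SE 0.10). Of 17 megakaryocyte genes 7 rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 0.000185, adjusted p = 0.0714 with an estimated correlation), with the platelet chemokine genes PPBP and PF4 at 4.44 (SE 0.11) and 2.06 (SE 0.21). The pan-leukocyte list had 7 of 24 genes rising and 0 falling (8 adjusted over the list alone) and did not pass (camera adjusted p = 0.0564, pointing up while the list's median was −0.02). ARHGDIB, LAPTM5 and LCP2, all signalling or membrane proteins abundant in blood cells, rose by 2.80 (SE 0.22), 2.14 (SE 0.14) and 1.48 (SE 0.14). Of 23 myeloid genes 5 rose and 0 fell (5 adjusted over the list alone, camera adjusted p = 0.111). One of them, AIF1 (0.85, SE 0.15), changed sign without the probe sets whose name ends in _x_at. The mannose receptor gene MRC1, also made by some endothelium, rose by 2.36 (SE 0.08) and lysozyme (LYZ) by 2.11 (SE 0.10).

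Notch genes went both ways in this comparison. Among the 10 ligands and receptors 3 rose and 4 fell (9 adjusted over the list alone; camera adjusted p = 0.747). NOTCH1 rose by 1.04 (SE 0.09), JAG1 by 0.82 (SE 0.12) and JAG2 by 0.48 (SE 0.09). DLK1, DLL3, NOTCH2 and NOTCH3 differed by −1.04 (SE 0.16), −0.89 (SE 0.07), −0.88 (SE 0.08) and −0.42 (SE 0.11). The NOTCH3 call ended with the replicate number as a block in the 2 paired groups (adjusted p = 0.0565), as did that of HEY2 below (adjusted p = 0.0546). Probe sets of 1 gene differed: the 4 of JAG1 gave −0.10, 0.54, 1.38 and 1.48, and the 2 of NOTCH3 gave −0.03 and −0.81. Those of NOTCH2 gave −1.38, −0.53, −0.26 and −1.36. Of 27 machinery genes 5 rose and 2 fell (7 adjusted over the list alone; camera adjusted p = 0.41, pointing up while the median was −0.02). The histone deacetylase gene HDAC1 rose by 0.73 (SE 0.11). With the block in the 2 paired groups the calls of PSENEN, SNW1 and ADAM10, which rose, and of CTBP1, which fell, ended. They also ended without both replicate 3 arrays (limma adjusted p = 0.2, 0.125, 0.133 and 0.177, in this order). Of 14 target genes 4 rose and 3 fell (10 adjusted over the list alone; camera adjusted p = 0.41). Fry, which does not compare a list with other genes, passed the target list upward (adjusted p = 0.00358) and the ligands and receptors downward (adjusted p = 0.0106). EFNB2 and ID1 rose by 1.49 (SE 0.20) and 1.42 (SE 0.16), CDKN1A by 0.86 (SE 0.09) and HEY2 by 0.31 (SE 0.08), whereas SOX9 differed by −0.94 (SE 0.16).

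HES1 was 0.31 higher in the sorted cells (SE 0.11, 95% confidence interval 0.07 to 0.55) and missed the threshold (adjusted p = 0.0614). Of 18 alternative fits HES1 was called in 7 and not in 11, with differences from 0.24 to 0.42. It passed with the replicate number as a block (adjusted p = 0.0435 with only the 2 paired groups and 0.0295 with all 8 arrays, H9 included by number), equal array medians (0.0382), quantile normalization (0.0408), trended and robust variance (0.048), array weights (0.0013) and without embryoid body replicate 2 (0.0263). The array weights of the third arrays were 8.15 and 4.40, against 0.27 to 0.55 for the other embryoid body and sorted cell arrays. That pass therefore leans on the arrays that lay between the first 2. Without both replicate 3 arrays the adjusted p of HES1 was 0.23. Its 3 probe sets did not move together: their differences were −0.06 (SE 0.10), 0.42 (SE 0.18) and 0.56 (SE 0.09). With every probe set tested on its own, a fit outside the 18 above, their limma adjusted p-values were 0.7, 0.129 and 0.00315. The last of these was therefore called alone, and the gene mean was not. The gene's values on the sorted cell arrays were 0.13, 0.35 and 0.15, against −0.24, 0.08 and −0.12 on the embryoid body arrays of the same numbers.

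**Figure D3:**
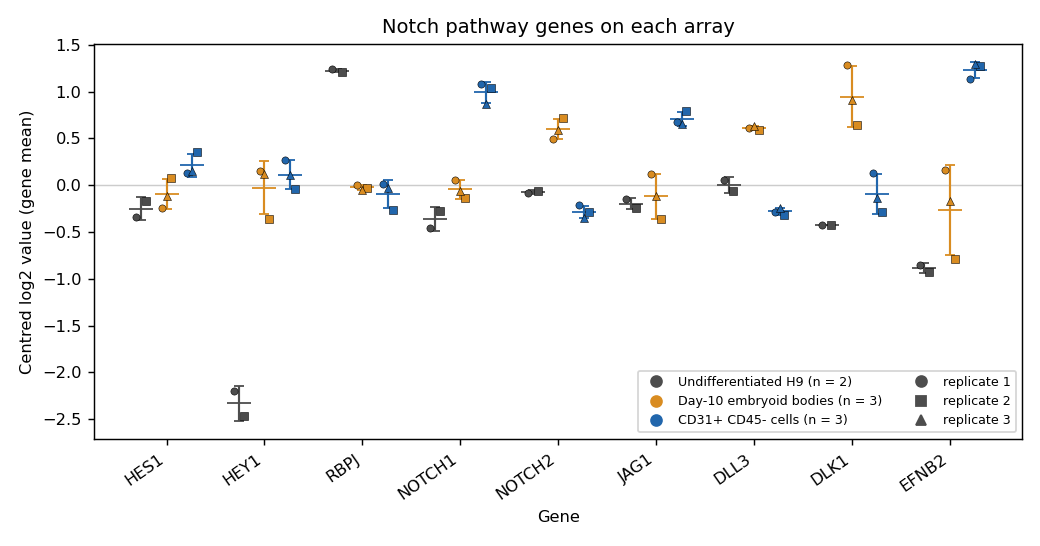
Centred log2 value (y axis, mean of each gene's probe sets) of 9 Notch pathway genes (x axis) on each array; symbols are replicates, colours are groups, horizontal bars are group means and error bars are SD (n = 2, 3 and 3). HEY1 and RBPJ separate the H9 arrays from the others, NOTCH1, JAG1 and EFNB2 are highest on the 3 sorted cell arrays, and HES1 lies between 0.13 and 0.35 on those arrays.

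In the mesenchyme list 18 of 31 genes fell and 5 rose (26 adjusted over the list alone; camera adjusted p = 0.000119, adjusted p = 0.0828 with an estimated correlation). Collagen COL6A3, lumican (LUM) and periostin (POSTN) differed by −3.14 (SE 0.17), −2.72 (SE 0.32) and −1.88 (SE 0.11), and S100A4 rose by 1.93 (SE 0.26). In the mesoderm list 9 of 17 genes fell and 0 rose (11 adjusted over the list alone; camera adjusted p = 2.71e-05, adjusted p = 0.108 with an estimated correlation), with ISL1 at −3.35 (SE 0.17), HAND1 at −3.24 (SE 0.22) and SNAI2 at −1.98 (SE 0.10). Among 21 cardiac genes 8 fell and 1 rose (10 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.231 with an estimated correlation). MYL7 and cardiac actin ACTC1 differed by −3.06 (SE 0.24) and −2.95 (SE 0.19), and MEF2C, a transcription factor of heart and also of endothelium, rose by 2.55 (SE 0.10). HOX genes fell in 6 and rose in 1 of 18 cases (7 adjusted over the list alone; camera adjusted p = 0.0138, adjusted p = 0.115 with an estimated correlation), with HOXC6 at −1.76 (SE 0.12). WNT pathway genes fell in 11 and rose in 1 of 29 cases (14 adjusted over the list alone; camera adjusted p = 0.000855, adjusted p = 0.0714 with an estimated correlation). FZD2, WNT5A and FZD7 differed by −2.38 (SE 0.24), −2.01 (SE 0.19) and −1.45 (SE 0.14).

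In the neuroectoderm list 14 of 25 genes fell and 0 rose (5 fell without both replicate 3 arrays; 16 adjusted over the list alone; camera adjusted p = 3.57e-05, adjusted p = 0.231 with an estimated correlation). The neuronal genes STMN2 and DCX differed by −3.37 (SE 0.98, adjusted p = 0.0353) and −2.73 (SE 0.85, adjusted p = 0.0446), and both calls ended with the block in the 2 paired groups (adjusted p = 0.0523 and 0.0549). Both were high on embryoid body arrays 1 and 3 only: STMN2 had 4.76 and 4.07 there against 0.14 on array 2. In the epithelium and trophoblast list 14 of 24 genes fell and 0 rose (17 adjusted over the list alone; camera adjusted p = 1.85e-05, adjusted p = 0.24 with an estimated correlation). Keratin KRT19 and the transcription factor gene TFAP2C differed by −2.70 (SE 0.82) and −1.64 (SE 0.10). In the pluripotency list 5 of 21 genes fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 0.0354, adjusted p = 0.435 with an estimated correlation), led by L1TD1 at −2.50 (SE 0.61), and its camera adjusted p was 0.0582 without the third arrays. Endoderm and liver genes went both ways, 4 of 24 rising and 3 falling (7 adjusted over the list alone; camera adjusted p = 0.13). HHEX, which this list shares with the hemogenic list, led it, followed by alpha-fetoprotein (AFP) at 2.46 (SE 0.68).

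Cell cycle genes were partly higher in the sorted cells, with 13 of 37 rising and 1 falling (16 adjusted over the list alone; camera adjusted p = 0.000435, adjusted p = 0.231 with an estimated correlation). UBE2C rose by 1.00 (SE 0.12), and cyclin E1 (CCNE1) differed by −0.91 (SE 0.26). Of the 27 immediate-early and stress genes 11 rose and 3 fell (14 adjusted over the list alone; camera adjusted p = 0.000603, adjusted p = 0.0989 with an estimated correlation), with NR4A2 at 1.61 (SE 0.11), DUSP5 at 1.24 (SE 0.20) and FOS at 1.12 (SE 0.16). The genes with the largest increases outside the lists were GNG11, a G protein subunit, at 5.06 (SE 0.10) and GMFG, an actin regulator of blood cells and endothelium, at 4.32 (SE 0.12). The other largest decreases were SST at −3.60 (SE 0.10) and the tubulin gene TUBB2B at −3.34 (SE 0.24).

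In all, 3128 genes differed between sorted cells and embryoid bodies (limma, adjusted p threshold 0.05), 1680 higher and 1448 lower, of which 307 and 182 differed at least 2-fold; 17 lists passed, 9 upward and 8 downward, 0 passed with camera at an estimated correlation, and fry passed 22. Without both replicate 3 arrays 1034 genes were called, 700 higher and 334 lower, 1030 of them among the 3128 and 389 among the 489 with at least 2-fold differences, and 16 lists passed. Besides the calls of PSENEN, SNW1, ADAM10 and CTBP1 given above, those of JAG2, NOTCH3, DLK1, HEY2, SOX9, STMN2, DCX, KRT19, L1TD1, AFP and CCNE1 ended without the third arrays. Leaving out the third sorted array alone left 1974 called genes. Leaving out the third embryoid body array alone ended the calls of NOTCH3, HEY2, STMN2, DCX, KRT19, L1TD1, AFP and CCNE1 (adjusted p = 0.0568, 0.0567, 0.115, 0.134, 0.111, 0.0688, 0.0823 and 0.104), and those of all of these except HEY2 also ended without at least 1 other array. On the GAPDH control probe sets, the 5′ minus 3′ difference was 1.64 ± 0.35 (SD, n = 3) in the sorted cells, −0.07 ± 0.35 (SD, n = 3) in the embryoid bodies and −0.21 ± 0.08 (SD, n = 2) in H9 cells, so that it moved with all of the differences between sorted cells and the other groups. Sorted cells against embryoid bodies gave an exact permutation p = 0.1 (two-sided), the smallest that 3 against 3 arrays allow. The corresponding difference of ACTB between sorted cells and embryoid bodies was −0.09.

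Fewer genes of sorted cells against embryoid bodies were also called within the lists without both replicate 3 arrays. Falling genes went from 5 to 1 in the pluripotency list, from 9 to 5 in the mesoderm list, from 8 to 3 in the cardiac list, from 14 to 6 in the epithelium and trophoblast list, from 6 to 2 among HOX genes and from 11 to 4 in the WNT list. They went from 4 to 2 among Notch ligands and receptors, from 2 to 0 in the Notch machinery and the endothelial list, from 3 to 0 among Notch targets, in the endoderm list and in the immediate-early list, and from 1 to 0 among hemogenic regulators and in the cell cycle list. Rising genes went from 13 to 3 in the cell cycle list, from 8 to 4 in the arterial, from 8 to 5 in the erythroid and from 5 to 3 in the myeloid list, from 5 to 1 in the Notch machinery, from 4 to 1 in the endoderm list, and from 1 to 0 among HOX genes and in the WNT list.

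The third comparison set the sorted cells directly against undifferentiated H9 cells. HES1 was higher by 0.46 (SE 0.12, adjusted p = 0.0206), a call that ended without the third arrays (adjusted p = 0.091) and without the first or the second H9 array (adjusted p = 0.176 and 0.0575), and its 3 probe sets gave −0.21, 1.10 and 0.51. NOTCH1 and HEY1 rose by 1.36 (SE 0.10) and 2.44 (SE 0.17), and RBPJ differed by −1.32 (SE 0.10). PECAM1 was higher by 3.31 (SE 0.09), and PTPRC differed by 0.06 (SE 0.07, adjusted p = 0.652). In total 2809 genes differed, 1311 higher and 1498 lower, of which 372 and 336 differed at least 2-fold. Without both replicate 3 arrays 1544 were called, 750 higher and 794 lower, 1541 of them among the 2809 and 642 among the 708 with at least 2-fold differences; without the first H9 array 1507 were called and without the second 1571. Of the 28 lists 17 passed, 12 upward and 5 downward, and the same 17 passed without both replicate 3 arrays. Camera with an estimated correlation passed 4: the endothelial list (adjusted p = 0.0486), the hemogenic regulators, the megakaryocyte list and the immediate-early and stress list (each adjusted p = 0.0457). Of the endothelial genes 31 of 38 rose and 1 fell, of the hemogenic regulators 16 of 25 rose and 1 fell, and of the pluripotency genes 16 of 21 fell and 0 rose. The limits given above for the endothelial and hemogenic lists, the sort by CD31 and the shared genes, hold here too. Between sorted cells and H9 cells the mean of the same 9 ribosomal RNA controls differed by −0.86 and the GAPDH 5′ minus 3′ value by 1.85. Both moved with all of these differences.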

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

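All tests of explanations in this part were chosen after the result was seen. On the GAPDH control probe sets, which are outside the comparisons of genes, the 5′ minus 3′ difference was 1.71 higher in the sorted cells than in the embryoid bodies. A shift in RNA quality or labelling common to all transcripts could give such a value, and it would move the ACTB control pair the same way by about as much. This pair differed by −0.086 between the same groups, which argues against a common shift. A cause particular to the GAPDH transcript or its probe sets stayed open, and no biological explanation was tested.

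The 9 ribosomal RNA control probe sets named HUMRGE, Hs18SrRNA or Hs28SrRNA, also outside the comparisons of genes, were lower in embryoid bodies than in H9 cells (mean −1.27). The M27830 controls, which that mean leaves out, went both ways. No explanation of this was tested.

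Replicate 3 of both groups lay between the first 2 on most probe sets that set these apart. Pooled material of replicates 1 and 2 could account for this: in those probe sets the median fraction of replicate 1 in the third array, on the linear scale, was 0.54 in the embryoid bodies and 0.56 in the sorted cells, although a pool predicts a single fraction and the embryoid bodies gave 0.59 where replicate 1 was higher, 0.45 where replicate 2 was, and list medians over 3 to 6 genes from 0.34 (hypoxia) to 0.66 (cardiac). An independent culture for replicate 3 with its own variation of equal size would leave a part off the line through the other 2. Simulated independent arrays gave a ratio of 0.726 for this part. The ratios of replicate 3 were 0.15 and 0.222, so they argue against an independent culture of that kind. The ratios of replicates 1 and 2 (0.628 to 1.589) are no separate reference, because distances among the same 3 arrays set them too. The ratios of replicate 3 were also above the 0.027 to 0.029 of simulated mixtures with little noise, so an exact pool was not shown. Another culture that happened to lie midway along a single axis of difference cannot be told apart from a pool by these values (position 0.556 and 0.61 on the log2 scale): the third arrays were nearer the linear mixture than the log2 midpoint (root mean square 0.185 against 0.418 and 0.246 against 0.299), but a culture with an intermediate mix of cells would be so too. The labels call all 3 arrays biological replicates, and if the third were pools, 2 independent samples per group would remain and the standard errors above would be too small.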

How the results depend on the processing

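The fits without both replicate 3 arrays, with the most variable probe set, without _x_at probe sets and with a block in the 2 paired groups only were chosen after the data were seen. The numbers of called genes were 2220 (embryoid bodies against H9 cells), 3128 (sorted cells against embryoid bodies) and 2809 (sorted cells against H9 cells). In this order they became 5176, 7250 and 5154 with array weights, which gave the third arrays weights of 8.15 and 4.40; 386, 489 and 708 with at least a 2-fold difference; 226, 332 and 547 with treat at 1.5-fold; and 835, 1034 and 1544 without both replicate 3 arrays. A fold minimum and treat are stricter by construction; why the counts moved without the replicate 3 arrays was not tested. The third count was 4322 with every probe set tested on its own, where more units were tested. Leaving out 1 array gave 743 to 2489, 1974 to 2955 and 1507 to 3117, and the counts of passing lists ran from 13 to 17, 16 to 18 and 17 to 18. Estimated correlations left 0, 0 and 4 of 14, 17 and 17 lists.

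With the replicate number as a block the counts were 1671, 2676 and 2320; this fit also put the H9 arrays in blocks by number, a pairing the data did not bear out, so the first and the last say nothing about pairing. It changed the call of no list. With the block in the 2 paired groups alone the second count was 2456; of the genes covered by the naming rule the calls of STMN2, FGF4, NOTCH3, PSENEN, SNW1, CTBP1, ADAM10, HEY2, DCX and TOP2A ended, that of HES1 was added, and no other changed. With all 8 arrays HOXB6 also lost its call, and STMN2, SNW1, HEY2 and TOP2A kept theirs. All other alternatives kept these counts within 1.5 times.

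Among 5938 values of 343 differences of genes covered by the naming rule, 5381 kept direction and side of the threshold, 541 lost the call, 12 gained one and 4 changed sign. Without both replicate 3 arrays 101 of the 343 lost it. The changes of sign were PECAM1 in embryoid bodies against H9 cells without H9 replicate 2 (0.011) or embryoid body replicate 1 (0.003), with a range of −0.049 to 0.011 over single arrays left out; PTPRC in sorted cells against H9 cells with the most variable probe set (−0.01); and AIF1 in sorted cells against embryoid bodies without _x_at probe sets (−0.145). The first 2 genes were called under none of these, and the cause was not tested. A lone H9 array was assumed to vary like the other groups.

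The brightest probe set per gene and the filter on dim genes were not run, since the centred values hold no levels; signal over background is therefore unknown for every gene.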

Other observations

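The tests of explanations and of other splits in this part were chosen after the result was seen, and the gene lists were fixed before. In the VEGF and angiopoietin list, which holds ligands and receptors, 7 of 18 genes rose and 3 fell in sorted cells against embryoid bodies (10 adjusted over the list alone; camera adjusted p = 0.0152, adjusted p = 0.338 with an estimated correlation). KDR, the main VEGF receptor of endothelium, rose by 2.90 (SE 0.33), TEK by 1.10 (SE 0.08) and FLT1 by 1.04 (SE 0.10). These genes are also members of the endothelial list, so the VEGF list is not a separate result. Between embryoid bodies and H9 cells the list did not pass (5 rose and 1 fell, 6 adjusted over the list alone; camera adjusted p = 0.0556), and PDGFA differed by −0.58 (SE 0.08). Of 26 genes of haematopoietic cytokine receptors and their signalling, 3 rose and 2 fell in the sorted cells (5 adjusted over the list alone; camera adjusted p = 0.587), with JAK1 at 1.76 (SE 0.07) and the stem cell factor receptor KIT at 0.98 (SE 0.10). In embryoid bodies against H9 cells 1 rose and 2 fell (3 adjusted over the list alone; camera adjusted p = 0.63), and IL6ST, a shared receptor subunit of the interleukin-6 family, rose by 0.84 (SE 0.07). Of 14 venous and lymphatic genes 6 rose and 2 fell in the sorted cells (8 adjusted over the list alone; camera adjusted p = 0.13), with EMCN at 1.84 (SE 0.23) and RELN at −2.38 (SE 0.26). In embryoid bodies against H9 cells 2 rose and 1 fell (3 adjusted over the list alone; camera adjusted p = 0.0969), RELN by 2.20 (SE 0.29). BMP and TGF-β genes went both ways in the sorted cells, 8 of 31 rising and 7 falling (15 adjusted over the list alone; camera adjusted p = 0.743, pointing up while the median was −0.06), with TGFBI at −1.65 (SE 0.12) and TGFBR2 at 1.12 (SE 0.08).

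Metabolic and ribosomal genes also differed. Of 17 cholesterol synthesis genes 8 fell and 0 rose in embryoid bodies against H9 cells (10 adjusted over the list alone; camera adjusted p = 9.51e-05, adjusted p = 0.108 with an estimated correlation), led by the sterol oxidase gene MSMO1 at −2.38 (SE 0.29). In sorted cells against embryoid bodies 2 rose and 3 fell (7 adjusted over the list alone; camera adjusted p = 0.87, pointing up while the median was −0.02), with LSS at −0.50 (SE 0.07). Ribosomal protein genes rose in 7 and fell in 0 of 20 cases in embryoid bodies (10 adjusted over the list alone; camera adjusted p = 0.000428, adjusted p = 0.171 with an estimated correlation), RPL10A by 0.69 (SE 0.08). They rose in 7 and fell in 2 cases in the sorted cells (12 adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.338 with an estimated correlation), RPS6 by 0.68 (SE 0.07). The hypoxia and glycolysis list passed in neither comparison. In embryoid bodies 5 of 26 genes rose and 2 fell (10 adjusted over the list alone; camera adjusted p = 0.63), and in the sorted cells 6 rose and 4 fell (11 adjusted over the list alone; camera adjusted p = 0.475). Hexokinase HK1 differed by −1.49 (SE 0.09) and 1.19 (SE 0.08) in these comparisons.

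Without both replicate 3 arrays, fewer genes of these lists were called. Among called members left unnamed above, APLNR (2.39) of the venous and lymphatic list lost its call in embryoid bodies against H9 cells (limma adjusted p = 0.191). EGLN3 (−1.34) of the hypoxia and FDPS (0.91) of the cholesterol list lost theirs in sorted cells against embryoid bodies (limma adjusted p = 0.11 and 0.0645). Each was larger in size than a member of its list named there. In sorted cells against embryoid bodies, rising genes went from 7 to 4 in the VEGF, from 6 to 3 in the venous and lymphatic, from 8 to 3 in the BMP and TGF-β, from 6 to 2 in the hypoxia and from 2 to 0 in the cholesterol list. Falling genes went from 3 to 0 in the VEGF, from 2 to 1 in the cytokine receptor, from 7 to 4 in the BMP and TGF-β, from 4 to 1 in the hypoxia, from 3 to 1 in the cholesterol and from 2 to 0 in the ribosomal list. In embryoid bodies against H9 cells, rising genes went from 5 to 1 in the VEGF, from 2 to 1 in the venous and lymphatic, from 5 to 2 in the hypoxia and from 7 to 2 in the ribosomal list, and falling genes from 8 to 5 in the cholesterol, from 2 to 1 in the hypoxia and from 1 to 0 in the venous and lymphatic list.

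Embryoid bodies of the same group differed in lineage markers. The mean of the neuroectoderm list was 0.99, 0.14 and 0.76 on arrays 1 to 3, and that of the endoderm and liver list was −0.56, 0.12 and −0.11. On the sorted cell arrays of the same numbers the endoderm and liver mean was −0.43, 0.86 and 0.39, and AFP had −0.59, 2.65 and 1.67.

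Blood transcripts were present in a fraction sorted as CD45-negative, and their origin is the pattern a biologist would most want to follow up. CD45-positive leukocytes carried through the sort could bring such transcripts, and the values of the pan-leukocyte list went both ways. In sorted cells against embryoid bodies PTPRC had an upper 95% bound of 0.035 and the list's median was −0.024. However, 7 of its 24 genes rose, among them ARHGDIB (2.80), LAPTM5 (2.14) and LCP2 (1.48). Against H9 cells the list passed upward (camera adjusted p = 0.00158, adjusted p = 0.208 with an estimated correlation). So did the myeloid list (0.0214 and 0.174 in the same tests), while PTPRC differed by 0.06 (SE 0.07). A comparison with whole embryoid bodies cannot show absence, so leukocytes stayed open. CD31-positive megakaryocyte or erythroid cells within the gate cannot be told apart from hemogenic precursors that express these genes, because bulk arrays do not say which cells hold a transcript (median 0.464 for the erythroid list and 0.086 for the megakaryocyte list). All of these remain hypotheses.

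For sorted cells against embryoid bodies, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many as 3128 called genes, and the highest of the others gave 0, also among the 4 splits that part all 3 pairs. With 10 splits no share under 0.1 can arise, so the splits are too few for this test.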
